A study of Homo sapiens and Mus musculus with 6 samples.

How the data were processed

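Total RNA of 6 cultured cell lines was labelled with biotin and hybridised to Illumina Ref-8 BeadChips, human version 2 for MCF7, MDA-MB231 and SUM159 and mouse version 1.1 for 67NR, 168 FARN and 4T1, per the labels' protocols. The deposited values are 1 probe intensity per array on a linear scale; scanner software, background step and normalization are not given in the sources used here. The lowest deposited intensity was between 87.2 and 118.2 per array, so a background or an added offset remained in the values. The 99th percentiles ran from 15113 to 23140 on the human arrays, so the arrays did not share 1 distribution. The labels describe the MCF7, 67NR and 168 FARN arrays as a replicate, but 1 array of each line was analysed here. MDA-MB231 cells were grown by a supplier's protocol and the others by standard protocols, per the labels, and media are not given in the sources used here.

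Of 20589 human probes, 6 had no value, 18326 had 1 gene symbol and 2257 none, giving 16586 genes, of which 1541 had several probes. Of 24613 mouse probes, 20984 had 1 symbol, 1 had several and 3628 none, giving 15967 genes, 3728 with several probes. Of the named human probes, 18309 had an identifier found in the RefSeq gene table of GRCh38.p14, and no symbol needed updating. Every deposited column belonged to 1 sample. Gene coordinates are not used here.

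Each species was quantile normalized separately, values below the highest array median (224.2 and 172.2) were set to it, and log2 was taken. The probe with the highest mean stood for its gene. A gene entered a comparison if above the floor on at least 1 of its 2 arrays. Differences were called at 4-fold, that is 2.0 on the log2 scale, with no test, since each line had 1 array. Writing folds as bounds where the dimmer value lay under 1.5 times the floor was decided after the data were seen. A gene list's median was placed among 10000 random lists of the same size matched on deciles of mean expression; percentiles under 2.5 were called low and the mirror range high, and lists with under 5 measured members got none. Counts of genes with 1 line apart were set against 1000 shuffles of values among lines within genes. Genes whose probes opposed each other by 2-fold were not to be ranked, and none was found.

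Before the data were examined, 22 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists covered line identity, epithelial junctions and keratins, mesenchymal genes, luminal and estrogen receptor genes, basal and myoepithelial genes, matrix proteases, integrins, cytokines and chemokines, metastasis genes from MDA-MB-231 sublines, interferon response, MHC class I, cell cycle, hypoxia and glycolysis, cholesterol and fatty acid synthesis, TGF-beta and BMP, Wnt, COPII coat, ribosomal proteins, and markers of leukocytes, endothelium, fibroblasts and adipocytes. Named per comparison were the 6 highest and lowest differences among genes above the floor on both arrays, the 4 brightest bounded genes per direction, the 5 leading genes with 1 line apart among those above the floor on all 3 arrays, and up to 4 members per list; some were left out for length. List members beyond that rule, the values of opposite-moving genes and the genes of the species comparison were chosen after their values were seen.

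Alternatives were the values as deposited, median scaling, the floor at the 40th or 60th percentile, no floor with an offset of 16, the mean of all probes, a 2-fold threshold and, for lists, unmatched random lists and only members above the floor on both arrays. Normexp background correction with an offset of 50 before quantile normalization was added after the data were seen.

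The steps were tested on simulated arrays made from 1 array per platform, with 200 genes changed. Without noise or normalization the differences implied by the simulated background were recovered. A first guard on the share of 6-fold genes called was not met, was loosened and was not met again, and a second on the size of the error was not met either. All were replaced after their outcome was seen by guards on recovery without noise and on bias under balanced changes. The cause of the second was traced to quantile normalization, which takes up part of a change when all changed genes go 1 way: bright unchanged genes then shifted by -0.12 (human) and -0.08 (mouse) on the log2 scale, and by -0.01 and -0.00 when changes were balanced. The simulated noise had an SD of 0.15 on the log2 scale. In the balanced human simulation, 34.0% of true 4-fold genes, 98.0% of 6-fold and 100.0% of 16-fold genes were called (9271 genes run). In the balanced mouse simulation the shares were 24.0%, 90.0% and 100.0% (9179 genes run). All these shares describe changed genes well above background and not dim ones. With background left in, the expected log2 difference of the true 4-fold genes was still 1.91 (human) and 1.85 (mouse), near but under 2.0. A background or offset left in the values compresses folds, most for dim genes. Whether the named folds understate true ratios was not tested, since they were picked as the largest on 1 array per line. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.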

Results

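Expression arrays of 6 breast cancer cell lines were compared, 3 human and 3 mouse, with 1 array per line. The series addressed lines that differ in their capacity to metastasise. The human lines were MCF7, a luminal, estrogen receptor positive line that metastasises weakly, and MDA-MB231 and SUM159, which lack the estrogen receptor and have a mesenchymal appearance. The mouse lines 67NR, 168 FARN and 4T1 descend from a common mammary tumour: 67NR forms primary tumours only, 168 FARN reaches lymph nodes and 4T1 spreads to distant organs. No line had a second array, so no difference below has a replicate check or a p-value, and the number of arrays limits the precision. The only spread that could be measured was the SD between different probes of a gene on the same 2 arrays. It holds no variation between repeated arrays or cultures, so it does not give the precision of a comparison. Its median was 0.22 to 0.25 on the log2 scale in the human comparisons and 0.15 to 0.16 in the mouse comparisons. The 95th percentiles were 1.01 to 1.06 and 0.56 to 0.59. This spread could be measured for 247 to 269 human and 1402 to 1445 mouse genes with several probes above the floor. Genes were called apart at 4-fold, and a gene at or below the intensity floor on 1 array has only a bound, written as "at least". The same is written where the dimmer value lay under 1.5 times the floor, near background, as for 43 of the 72 differences named as above the floor on both arrays. The floor was an intensity of 224.2 on the human and 172.2 on the mouse arrays. Between 9041 and 9048 of 16586 genes lay above it on the human arrays, and between 8689 and 8738 of 15967 on the mouse arrays. List medians over members above the floor on both arrays leave out every member at or below the floor on 1 array, which the difference itself decides. A call that ended there therefore does not count against its direction, and a call that turned there describes only the members kept.

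Genes that identify the lines were read first. ESR1, the estrogen receptor, had an intensity of 2757 in MCF7 and lay below the floor in MDA-MB231 and SUM159. Its target TFF1 read 56204 in MCF7, 340.2 in MDA-MB231 and below the floor in SUM159. VIM, the intermediate filament vimentin, read 227.8 in MCF7, just over the floor, against 48256 in MDA-MB231 and 46250 in SUM159. The CDH1 probe (E-cadherin) read only 250.5 in MCF7, so it checked little. KRT18 was bright in all 3 human lines, at 57646 in MCF7, 33618.5 in MDA-MB231 and 10806.9 in SUM159. Among the mouse lines, Cdh1 read 1559 in 4T1 and lay below the floor in 67NR and 168 FARN. Krt18 read 15371 in 4T1, 172.8 in 168 FARN and below the floor in 67NR. Vim was bright in all 3 mouse lines, at 35230 in 4T1, 48387 in 67NR and 39560 in 168 FARN.

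MDA-MB231 lacked much of the epithelial and luminal expression of MCF7 and carried a mesenchymal one. Of 25 measured genes of epithelial junctions and keratins, 10 were at least 4-fold lower in MDA-MB231 and none was 4-fold higher. RAB25, a GTPase of apical recycling, was at least 64.8-fold lower, and the tight junction claudin CLDN3 was at least 51.2-fold lower. The list's median log2 difference was -1.81, below all 10000 random lists of matched expression. Of 21 luminal and estrogen receptor genes, 11 were at least 4-fold lower, with a median of -3.52 that was also below all random lists. It ran from -4.05 to -1.75 over all settings. TFF1 was 165-fold lower, and the luminal transcription factors FOXA1 and GATA3 were at least 47.0-fold and 32.1-fold lower.

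In the opposite direction, 7 of 17 mesenchymal genes and regulators of epithelial-mesenchymal transition were at least 4-fold higher in MDA-MB231 than in MCF7. Their median was 1.70, above all random lists, and ran from 0.75 to 2.11 over the settings that gave a value. Only 4 members lay above the floor on both arrays, too few for a median under that setting. VIM was at least 212-fold higher and the receptor tyrosine kinase AXL at least 81.3-fold higher. Matrix proteases and their inhibitors had a median of 0.98, which ran from 0.29 to 1.14 over all settings. Of 15 measured, 4 were at least 4-fold higher, among them PLAU (urokinase), at an intensity of 10247 against a value below the floor in MCF7. Cell cycle and DNA replication genes had a median of 1.06, with TYMS and CDC20 past 4-fold among 23 measured. Interferon response genes were lower as a group, with a median of -1.05 over 20 genes and 3 past 4-fold, including IFITM1 and IRF9. Of the 20, 6 were higher in MDA-MB231. Genes reported for bone and lung metastasis of MDA-MB-231 sublines had a median of 0.84 over 10 measured members, with IL11 and CCN2 past 4-fold higher and CXCR4 at least 4.06-fold lower. That list was chosen from derivatives of this line, so it is not independent of it. Its percentile fell inside the random range, to 95.5 (median 0.80) over the 5 members above the floor on both arrays. Without a floor it fell to 97.1 (median 0.15). The TGF-beta and BMP list had a median of 0.47 (percentile 99.6). Over the 9 members above the floor on both arrays it was -0.26 (percentile 12.9), and 8 of the 9 members left out were higher in MDA-MB231.

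Over all 10109 genes measured in MDA-MB231 or MCF7, 278 were at least 4-fold higher in MDA-MB231 and 307 were lower. Median scaling gave 225 higher and 360 lower. Besides VIM, the genes with the largest differences among those above the floor on both arrays were EMP3 (62.2-fold higher), ARHGDIB (61.7-fold), SPANXB1 (at least 56.0-fold), CAVIN1 (51.9-fold) and PHLDA1 (51.5-fold). On the lower side, TFF1 was followed by CRABP2, which binds retinoic acid (53.3-fold), CLDN3, STARD10 (42.9-fold), the interferon-induced IFI27 (42.6-fold) and TPD52L1 (39.2-fold). Bounds gave GPX1, the glutathione peroxidase, at least 152-fold higher, IGFBP7 at least 148-fold and ANXA1 at least 100.1-fold. IGFBP5 was at least 88.9-fold lower.

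SUM159 also had lower epithelial and luminal and higher mesenchymal expression than MCF7. Of 25 epithelial genes, 14 were at least 4-fold lower, with a median of -2.42, and 10 of 21 luminal genes were lower, with a median of -1.96. Both medians lay below all random lists. KRT19, a simple-epithelium keratin, was at least 261-fold lower, TFF1 at least 251-fold and the protease inhibitor SPINT2 at least 131-fold. The mesenchymal list had a median of 2.22 with 10 of 19 genes past 4-fold, including VIM (at least 203-fold), NNMT (at least 65.0-fold) and AXL, and CDH2 (N-cadherin) read 6301 in SUM159 against a value below the floor in MCF7.

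Other groups separated SUM159 from MCF7 as well. Hypoxia and glycolysis genes had a median of -1.25, with 5 of 18 at least 4-fold lower, among them ANGPTL4, ALDOC, BNIP3 and ENO2. Interferon response genes had a median of -0.72 over 21 genes, 6 of them higher in SUM159, with ISG15, IFIT1, IRF9 and OAS1 past 4-fold lower. This median was -0.32 and inside the random range (percentile 4.92) over members above the floor on both arrays. MHC class I genes had a median of 0.94, and HLA-B and the immunoproteasome subunit PSMB8 were past 4-fold among 13 measured; the percentile was 96.6 over members above the floor on both arrays. Fibroblast marker genes had a median of 1.05 over 6 measured members, with DCN at 2360 and COL1A1 at 1541 in SUM159. These fibroblast values stood beside the mesenchymal ones in the same line. Cell cycle genes (median -0.03, percentile 38.1) and TGF-beta and BMP genes (median 0.10, percentile 67.6) were not called in SUM159 against MCF7. The matrix protease list (median 0.23, percentile 97.7) and the metastasis list (median 0.24, percentile 98.0) were barely outside the random range. The protease percentile was 91.9 against unmatched random lists, with the same median, and 91.5 over members above the floor on both arrays, with a median of 0.38. The metastasis list returned inside it under 6 alternatives, with medians between 0.13 and 0.28. Over the 5 members above the floor on both arrays its median was -1.76 (percentile 0.065), and 9 of the 10 left out were higher in SUM159.

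In all, 327 of 10164 genes were at least 4-fold higher in SUM159 than in MCF7 and 295 were lower, or 312 and 315 with the values as deposited. TGFBI, a matrix protein induced by TGF-beta, was at least 155-fold higher. Among genes above the floor on both arrays it was followed by the homeobox gene IRX2 (47.8-fold), the tropomyosin TPM2 (44.4-fold), TMEM158 (at least 38.2-fold) and the mitochondrial superoxide dismutase SOD2 (35.1-fold). Lower were IFI27 (71.2-fold), MLPH (46.9-fold), FOXA1 (at least 42.8-fold), EFHD1 (at least 41.0-fold), CRIP2 (35.2-fold) and BAMBI (29.7-fold). GSTP1, a glutathione transferase, was at least 156-fold higher and GPX1 at least 124-fold.

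**Figure D1:**
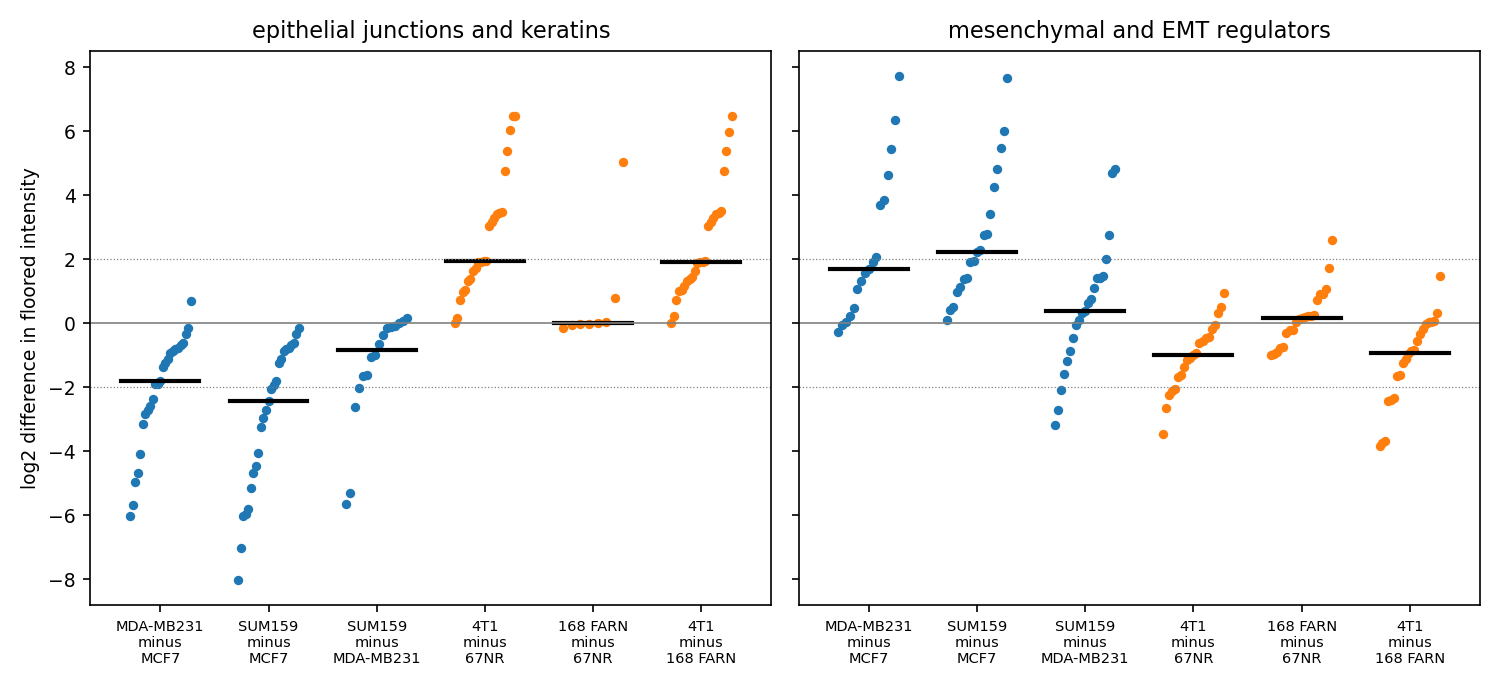
Log2 differences in floored intensity (vertical axis) of each measured member (points) of the epithelial and mesenchymal lists in the 6 comparisons, with list medians as bars, human in blue and mouse in orange; dotted lines mark 4-fold. Epithelial medians were -1.81 and -2.42 in MDA-MB231 and SUM159 over MCF7, and 1.94 in 4T1 over 67NR.

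MDA-MB231 and SUM159 were closer to each other than either was to MCF7. Across genes, Spearman's rho was 0.844 between them, 0.762 between MDA-MB231 and MCF7 and 0.744 between SUM159 and MCF7; genes are not independent replicates. Of 9904 genes, 189 were at least 4-fold higher in SUM159 than in MDA-MB231 and 156 were lower. Under median scaling these counts were 222 and 121. IRX2 was 81.5-fold higher in SUM159, TSC22D3, a glucocorticoid-induced leucine zipper protein, 63.5-fold, TPM2 42.4-fold, NUPR1 at least 33.9-fold and TRIB3 31.5-fold. FBLN1 was at least 28-fold higher by its brightest probe, but under 4-fold when its probes were averaged. ARHGDIB was 41.3-fold lower, the phosphatase DUSP4 30.0-fold and PLAU 19.3-fold.

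Cell cycle genes were lower in SUM159 than in MDA-MB231, with a median of -0.94 over 23 genes and TYMS, AURKB and CDK1 past 4-fold. MHC class I genes had a median of 0.62 and cytokines and chemokines a median of 0.28 (percentile 98.9), with IL1A, CXCL8 and CXCL2 past 4-fold higher and IL11 past 4-fold lower. Hypoxia and glycolysis genes had a median of -0.52. The fibroblast list had a median of 1.01 over 6 members. Epithelial genes were lower still in SUM159 (median -0.83, 4 of 16 past 4-fold) and mesenchymal genes slightly higher (median 0.39). The mesenchymal members went both ways: CDH2, NNMT and SPARC were higher in SUM159, and S100A4, CAV1 and CDH11 higher in MDA-MB231. Epithelial, mesenchymal and TGF-beta (median -0.44) medians all returned inside the random range over members above the floor on both arrays, at percentiles of 8.87, 96.0 and 30.1. The TGF-beta median did so too with the floor at the 40th percentile (4.25) and without a floor (8.12).

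Counted over all 3 human lines and 10615 genes, MCF7 stood at least 4-fold above both other lines for 206 genes and below both for 125. Shuffling values among lines within genes gave means of 137.9 and 64.1. Such shuffling spreads the same genes evenly over the lines, so its mean lies near the average count of the 3 lines. A line above it only had more genes than that average. MDA-MB231 stood above both others for 83 genes and below for 30, and SUM159 for 125 and 36. IFI27, CRIP2, STARD10, the histone gene H2AC18 and the collagen receptor DDR1 led the genes above both others in MCF7 among those above the floor on all 3 arrays. ASS1, which makes argininosuccinate, and TXNIP were at least 24.6-fold and 10.9-fold below both others in MDA-MB231, and MLPH, MAPK13 and the tetraspanin CD9 were 14.2-fold, at least 11.0-fold and 10.1-fold below both in SUM159. Among 9658 genes measured in both comparisons with MCF7, 125 were higher and 206 lower in both MDA-MB231 and SUM159. These are by definition the genes with MCF7 below and above both other lines, not a second result. Independent lists would share 7.51 and 9.38 genes, values that ignore the shared MCF7 array, and shuffled lines 63.9 and 116.4. Both comparisons used the 1 MCF7 array, which could not be split, so its own error enters both.

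**Figure D2:**
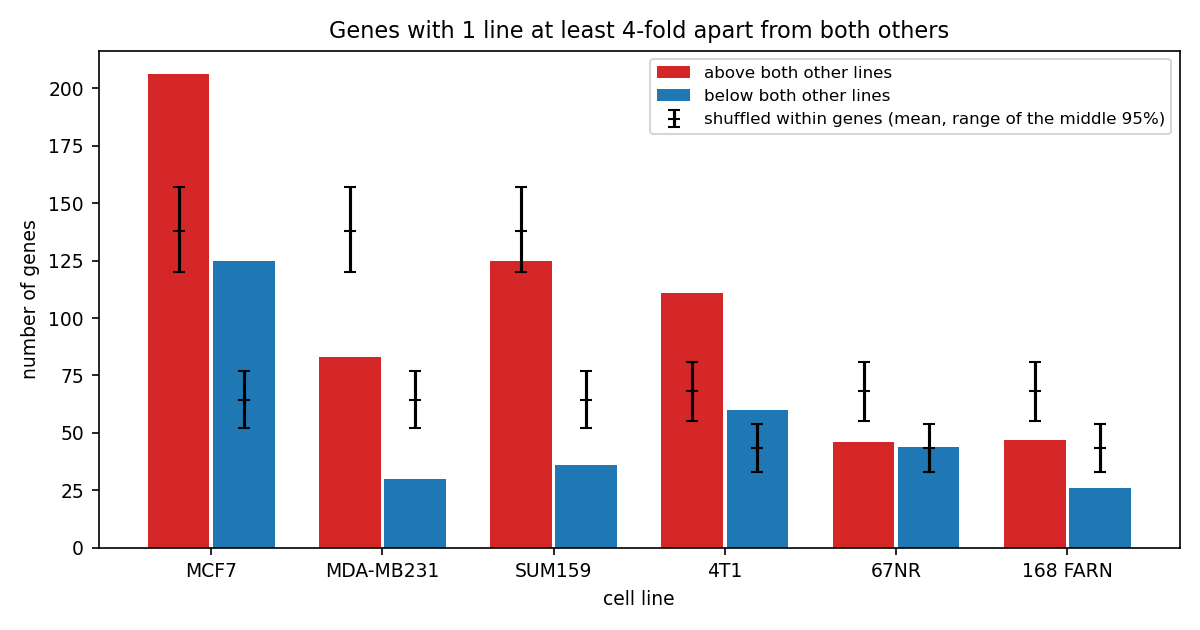
Number of genes (vertical axis) at least 4-fold above (red) or below (blue) both other lines of the species, per line; black marks give the mean and the middle 95% of 1000 shuffles within genes. MCF7, with 206 and 125 genes, and 4T1, with 111 and 60, exceeded the shuffled means in both directions. The shuffled mean lies near the average count of the lines, so some line exceeds it whenever the counts differ.

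The mouse lines showed the epithelial group in the most metastatic line. Of 24 epithelial genes measured, 11 were at least 4-fold higher in 4T1 than in 67NR and none was 4-fold lower. Krt8 was at least 88.8-fold higher, Krt18 at least 89.3-fold, and the claudins Cldn4 and Cldn3 at least 65.5-fold and 41.4-fold. The median was 1.94, above all random lists. The mesenchymal list had a median of -1.0, with 5 of 21 genes past 4-fold: the transcription factors Zeb1, Twist2 and Prrx1, Cav1 and S100a4. Vim was not among them.

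Cytokines differed in both directions between 4T1 and 67NR. The granulocyte growth factor Csf3, Cxcl16 and Ccl5 were at least 4-fold higher in 4T1, and Ccl7, Cxcl12, Ccl2 and Il33 at least 4-fold lower. The list's median was 0.36 (percentile 99.6), or 0.17 (percentile 90.5) over members above the floor on both arrays. Hypoxia and glycolysis genes had a median of 0.78 and MHC class I genes one of 0.76, both above all random lists, with Aldoc, Eno2, Psmb8, H2-T23 and Psmb10 past 4-fold. Matrix proteases had a median of -0.42 (percentile 0.12), although Plau was past 4-fold higher. The metastasis list had a median of -0.39 (percentile 1.09), which returned inside the random range under 4 alternatives besides the members above the floor on both arrays, and Vcam1 was past 4-fold higher. The TGF-beta and BMP list had a median of 0.25 (percentile 98.5, or 96.9 with the values as deposited), with Bmp7 past 4-fold. Of the fibroblast markers, Pdgfra read 2182 in 67NR and 541.5 in 4T1.

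In total 195 of 9720 genes were at least 4-fold higher in 4T1 than in 67NR and 144 were lower. Wfdc2, a secreted protease inhibitor of epithelia, was at least 264-fold higher and Krt7 at least 195-fold. Tnnt2 was at least 35.5-fold and Krtcap3 at least 25-fold higher. Inmt, a methyltransferase, was at least 180-fold lower, Aebp1 at least 103-fold, the homeobox gene Rhox5 at least 99.2-fold and the mucin-like protein Pdpn at least 97.0-fold. Epb41l3 was at least 50.1-fold lower by its brightest probe but under 4-fold when its probes were averaged. The basal keratin Krt14 was at least 40.8-fold higher.

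168 FARN was nearer to 67NR than 4T1 was, with a rho of 0.882 against 0.831, and of 9571 genes 113 were higher and 97 lower by 4-fold. Epithelial genes did not shift as a group (percentile 51.1, 8 measured), yet Krt8 was at least 32.6-fold higher in 168 FARN, at 6934, while its usual partner Krt18 stayed at 172.8. Interferon response genes had a median of 1.14 over 15 genes, above all random lists, with none past 4-fold. MHC class I genes had a median of 0.42 (percentile 99.5, or 94.2 over members above the floor on both arrays), with Psmb8 past 4-fold. Hypoxia and glycolysis genes had a median of 0.54, although Egln3 was 8.53-fold lower. Cell cycle and cholesterol synthesis genes had medians of -0.43 and -0.53, with no gene past 4-fold in either. Integrins had a median of 0.65 over 9 genes, with Itgb4 past 4-fold; the median was 0.15 with the floor at the 40th percentile and 0.13 without a floor, both inside the random range.

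Beyond these lists, Igfbp7 was at least 107-fold lower in 168 FARN than in 67NR, at 173.5 against 18547. Ecrg4 was 27.1-fold higher, Crip1 at least 24.9-fold, Sdhaf4 at least 22.3-fold and the basement membrane collagen Col18a1 20.9-fold. Inmt was 15.2-fold lower and Serpinh1, the collagen chaperone, 13.2-fold. The casein Csn3 was at least 36.9-fold lower and the protease Mmp3 at least 17.2-fold. By their brightest probes Vldlr was higher by a log2 difference of at least 5.32, Ctsa was at least 23-fold higher and Ptpn22 at least 12.7-fold lower, but each was under 4-fold when probes were averaged.

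Compared with 168 FARN, 4T1 again carried the epithelial group, with 10 of 24 genes at least 4-fold higher and a median of 1.91. The mesenchymal median was -0.92, and 6 of 22 genes were past 4-fold, including Cav1, Mmp2 and Zeb1. Cytokines had a median of 0.61, cell cycle genes 0.70 and cholesterol synthesis genes 0.57. Interferon response and MHC class I genes were lower in 4T1, with medians of -0.61 and -0.46. Fibroblast markers had a median of -0.94 over 5 genes, with Col1a1 at 1148 in 168 FARN and below the floor in 4T1. Of 9675 genes, 175 were higher and 128 lower in 4T1. Igf2, a fetal growth factor, was at least 279-fold lower, at 191.7 against 53546, and Rhox5 at least 107-fold, Serpinf1 at least 66.9-fold and the interferon-induced Ifi27l2a at least 65.3-fold. Wfdc2 was at least 211-fold higher, Igfbp7 at least 99.3-fold and Krt18 at least 88.9-fold. Tubb2b was at least 29.3-fold higher by its brightest probe, but under 4-fold when probes were averaged.

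Over 10176 mouse genes, 4T1 stood above both other lines for 111 and below both for 60. 67NR did so for 46 and 44 genes, and 168 FARN for 47 and 26. Shuffling gave means of 68.4 and 43.2, again near the average count of the lines. Tns4 and Tnnt2 were at least 22.6-fold and 30.1-fold above both others in 4T1, Slpi and Cox6a2 8.50-fold and 10.8-fold above both in 168 FARN, and Mustn1 and Ly6c1 8.99-fold and 6.67-fold above both in 67NR. Of 9115 genes measured in both comparisons with 67NR, 44 were higher and 46 lower in both 4T1 and 168 FARN. These are by definition the genes with 67NR below and above both others. Independent lists would share 1.61 and 1.53, values that ignore the shared 67NR array, and shuffling gave 43.1 and 47.6.

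Human and mouse lines were set side by side through 5948 shared gene symbols, a match by name and not by curated orthology. Lower in both MDA-MB231 and SUM159 than in MCF7 and higher in 4T1 than in 67NR were 15 genes, against 2.54 for independent lists. CLDN3, CLDN7, JUP, KRT8, KRT19 and RAB25 were among them, together with KRTCAP3, STARD10 and TPD52L1. Genes going the same way were few: CTSC, KRT7 and LDHB were higher in both species, against 1.92 for independent lists, and CRIP2, CXCL12 and PHLDA3 lower in both, against 1.33. CDA, EMP3, GLIPR1 and GSDME were higher in the human lines and lower in 4T1, against 1.0. Each of these groups, also those going the same way, exceeded its value for independent lists. An excess alone therefore does not set opposite movement apart. Both human comparisons again used the same MCF7 array, so its error enters both. All 3 contrasts were between lines of higher and lower metastatic capability, and the difference between species was not tested.

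Across all lists and comparisons, 116 medians had a percentile, of which 27 were high and 22 low where a nominal 5% gives 5.80. Among 200 unchanged lists on simulated arrays, 7.5% were called on the human and 4.5% on the mouse platform. Those lists held random genes with independent noise, so they do not calibrate lists whose genes vary together. Some lists also share members, and the comparisons within a species share arrays. COPII vesicle coat and cytoplasmic ribosomal protein lists were called in no comparison under any setting run. Many human ribosomal probes read near the top of the scale. RPL30 read 56838 in MDA-MB231 and 59439 in MCF7, where the highest deposited intensities were 61556 and 63440. Whether a difference could show there was not tested. Basal and myoepithelial, Wnt and endothelial lists were not called with the settings used here, but some alternatives put them outside the random range. The Wnt percentile reached 99.3 in MDA-MB231 over MCF7, 0.34 in SUM159 over MDA-MB231, 98.8 in 168 FARN over 67NR and 99 in 4T1 over 168 FARN. The basal list reached 0.97 in SUM159 over MCF7 and 97.9 in 4T1 over 168 FARN, where the endothelial list reached 99.4. COPII medians lay between -0.15 and 0.18. The line identity list was low in MDA-MB231 (-0.78) and SUM159 (-1.68) against MCF7. The luminal list was not called in any mouse comparison. Leukocyte and adipocyte lists had too few measured members for a percentile; their brightest genes were LAPTM5, at 1222 in MDA-MB231, and FABP4, at 281.5 in SUM159.

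**Figure D3:**
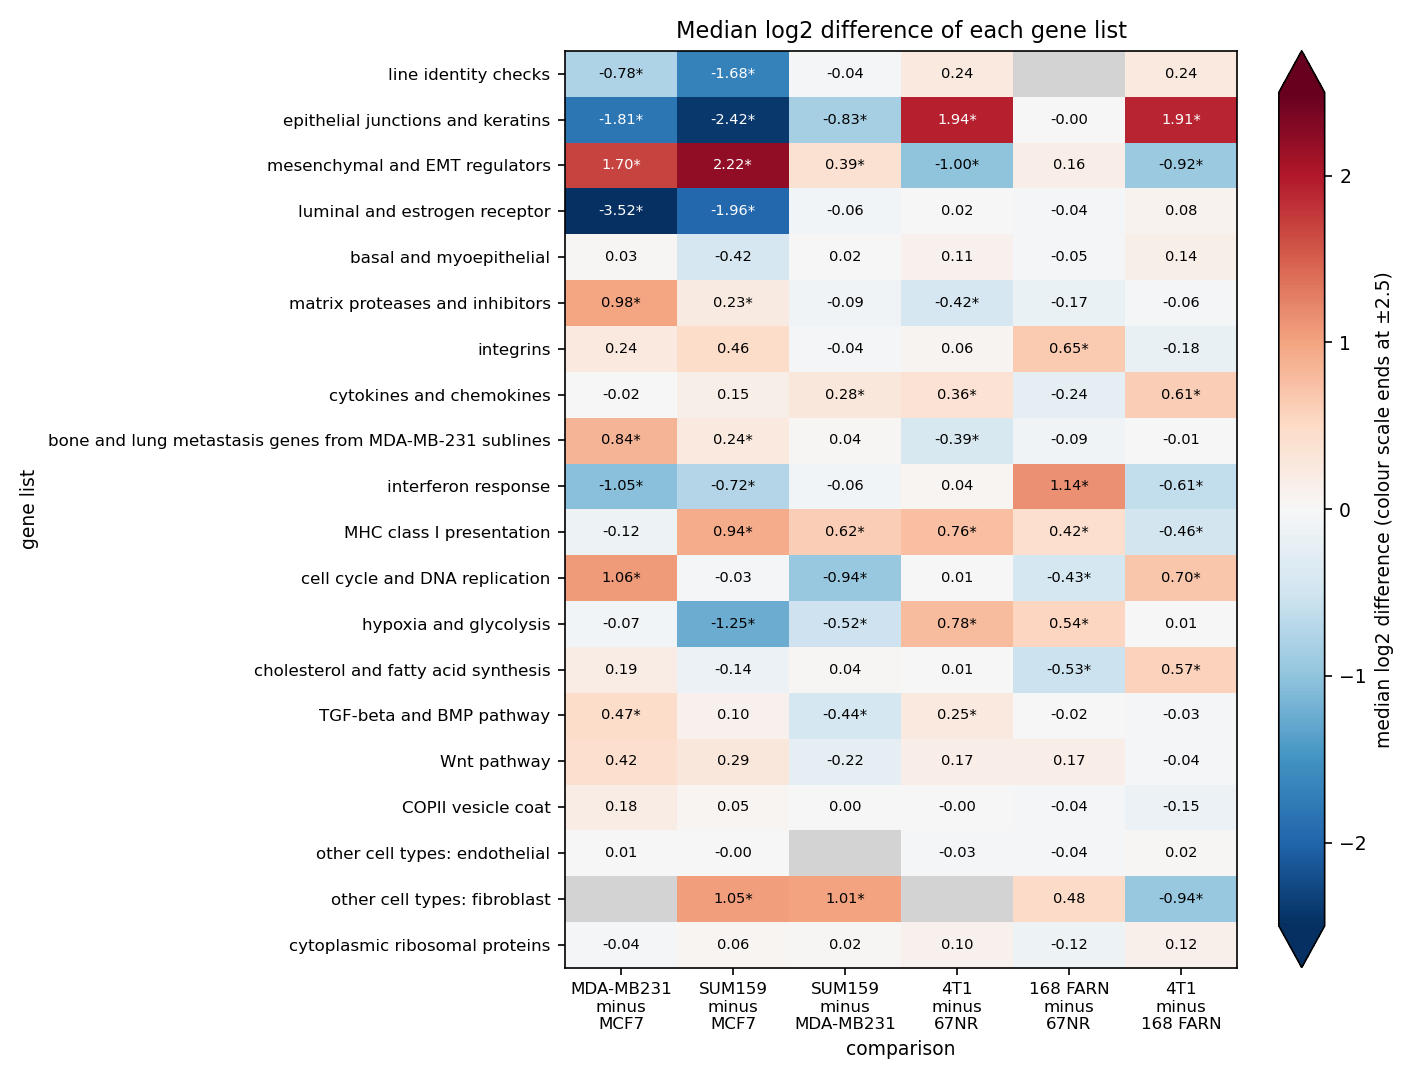
Median log2 difference of each gene list (vertical axis) in each comparison (horizontal axis), as colour and number; an asterisk marks a median outside the middle 95% of 10000 random lists matched on expression, and grey cells had under 5 measured members. The epithelial list ran from -2.42 in SUM159 over MCF7 to 1.94 in 4T1 over 67NR.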

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

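The tests of fibroblasts in 67NR, of leukocyte RNA in MCF7 and of dim probes for the interferon genes were chosen after the results were seen, and the glucocorticoid and ATF4 lists were chosen after TSC22D3, TRIB3 and NUPR1, which they leave out, had been seen.

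Lists moved in opposite directions in the 2 species, a difference that was not tested: the median in 4T1 over 67NR was 1.94 for epithelial and -1.0 for mesenchymal genes, each opposite to both human lines over MCF7. For the epithelial genes, the smallest absolute median over both other scalings and the 3 comparisons was 1.75. The choice among these scalings therefore did not make the pattern. Median scaling moves all genes of an array alike, random lists included, so it could hardly have ended the call. The normalization behind the deposited values is not given, so a bias already in them could not be tested. Dim probes were argued against only for members above the floor on both arrays, with a smallest absolute median of 1.93. That filter kept 16 members and left out 9 in MDA-MB231 over MCF7. It kept 7 and left out 18 in SUM159 over MCF7, and kept 7 and left out 17 in 4T1 over 67NR. Of those kept, Krt8 and Cldn4 read only 1.23 and 1.11 times the floor in 67NR. For the members left out the test cannot decide. Fibroblasts in the 67NR culture would bring their abundant collagens, but the brightest of Col1a1, Col1a2 and Col3a1 there read 160.7, below the floor, while Col1a1 read 1148 in 168 FARN; the markers Pdgfra (2182), Dcn (725.2) and Pdgfrb (339.1) did lie above the floor in 67NR. A difference between the lines themselves stays open as a hypothesis, with 1 array per line.

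The matrix protease median was -0.42 in 4T1 over 67NR and positive in both human lines over MCF7, untested, and the SUM159 percentile was 91.9 against random lists not matched on expression. The metastasis list, at -0.39 in 4T1 over 67NR, was also opposite to both human lines and untested. Its percentile was inside the random range under 6 alternatives in SUM159 and under 4 in 4T1. Over members above the floor on both arrays it was 0.065 in SUM159, on the low side, and 8.17 in 4T1.

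TSC22D3 was on opposite sides of MCF7 in the other human lines, by -2.77 on the log2 scale in MDA-MB231 and 3.22 in SUM159, and TRIB3 and NUPR1 were also high in SUM159. Lists of other glucocorticoid-induced genes and of other ATF4 target genes were fixed before their values were seen, and each lay at percentile 100 in SUM159 against both lines, the lower of its 2 values. The smallest median over both lists and both other scalings was 0.74, a test with the same limits as for the epithelial genes. A glucocorticoid in the medium and an amino acid stress response may therefore both contribute, but the medium is not given in the sources used here and line and culture are confounded.

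Interferon response genes were higher as a group in MCF7 than in both other human lines. The members were mixed, with 6 of 20 higher in MDA-MB231 and 6 of 21 higher in SUM159. Other scalings left a smallest absolute median of 0.71, with the same limits as for the epithelial genes. Leukocyte RNA was argued against because none of 10 leukocyte genes passed the floor in MCF7, the brightest reading 213.8. Over the 17 members above the floor on both arrays the median was -0.98 for MDA-MB231, which argues against dim probes for those members only. For SUM159 the median was -0.32, inside the random range. Dim probes cannot be told apart from a difference there, because that test leaves out the members that fell to the floor. Under the rule written beforehand for the epithelial genes, a percentile inside the random range would have counted for dim probes. The interferon rule, written afterwards, took it as undecided, so no outcome could count for dim probes. A difference between lines stays untested.

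Among the mouse lines, Igf2 was on opposite sides of 67NR, by -4.41 in 4T1 and 3.71 in 168 FARN. Serpinf1 differed by -3.73 and 2.33, and both genes read under 1.5 times the floor in 4T1. Sumo3 differed by 2.78 in 4T1 and by -2.34 or further in 168 FARN, a bound because it lay below the floor there. These differences were not tested.

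Probes without a single gene name, which entered no comparison, also held 4-fold differences: 40 between MDA-MB231 and MCF7, 50 between SUM159 and MCF7 and 32 between SUM159 and MDA-MB231. In mouse there were 36 between 4T1 and 67NR, 20 between 168 FARN and 67NR and 39 between 4T1 and 168 FARN.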

How the results depend on the processing

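Normexp background correction was chosen after the data were seen; the other alternatives were planned. With 1 array per line no replicate could be left out and no groups could be split. No paired analysis was possible because each line had 1 array and no result came from a test. Counts of genes apart in the 6 comparisons stayed within 1.5 times under all alternatives but the 2-fold threshold, which by construction gave 2210 for MDA-MB231 and 2150 for SUM159 over MCF7, 1481 for SUM159 over MDA-MB231, 1173 for 4T1 and 911 for 168 FARN over 67NR, and 1113 for 4T1 over 168 FARN. It gave 2465 human and 1315 mouse genes with 1 line apart. For shared symbols it gave 24 higher in both species, 33 higher in human and lower in 4T1, 93 lower in human and higher in 4T1, and 29 lower in both. Normexp gave 6, 9, 26 and 6 for the same groups and 49 genes, not 30, with MDA-MB231 below both other lines, and median scaling 5 lower in both. Without a floor, rho was 0.854 (MDA-MB231 and MCF7), 0.842 (SUM159 and MCF7) and 0.894 (SUM159 and MDA-MB231). That setting took in all 16586 human genes, where the main one used 10615, so floor and gene set changed together. List medians without a floor likewise took in members below the floor on both arrays. Over members above the floor on both arrays, the TGF-beta and BMP median in MDA-MB231 over MCF7 was -0.26 (percentile 12.9). The metastasis median in SUM159 over MCF7 was -1.76 there (percentile 0.065). Both had the other sign. Of the members left out, 8 of 9 and 9 of 10 were higher. The random lists passed the same filter, so the low metastasis percentile describes the 5 members kept. List calls numbered 49 of 116 and between 33 of 99 (members above the floor on both arrays) and 54 of 109 (60th percentile floor) otherwise. Of the 120 named gene differences, 6 went under 4-fold with the mean of all probes and none under another alternative. Median scaling moved the median of all genes in SUM159 over MDA-MB231 to 0.16 from -0.01. Signal over background limits dim genes, whose folds may be understated or are bounds.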

Other observations

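The genes named here were chosen after their values were seen. Of the glucocorticoid list, FKBP5 was 9.78-fold, KLF9 9.29-fold and CEBPD 7.74-fold higher in SUM159 than in MCF7, and DUSP1 read 10168 against 1012. Of its 14 measured members 10 were at least 2-fold higher and none 2-fold lower, with a median of 1.96, and against MDA-MB231 the median was 0.72 over 16, of which 6 were at least 2-fold higher. The metallothionein MT2A, also on the list, read 48256 in SUM159 and 52962 in MDA-MB231. Of 23 measured ATF4 targets, 19 were at least 2-fold higher in SUM159 than in MCF7 and 18 higher than in MDA-MB231. ASNS, which makes asparagine, was 12.2-fold and 14.4-fold higher, PSAT1 of serine synthesis 27.0-fold and 4.59-fold, and the stress transcription factor DDIT3 10.3-fold and 3.17-fold. PCK2 and MTHFD2 were 14.3-fold and 10.3-fold higher than in MDA-MB231. No gene was on both lists.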
